A study of Mus musculus with 16 samples.

How the data were processed

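The 16 samples were sections of formalin-fixed, paraffin-embedded tissue of wild-type mice, 2 male and 2 female samples at each of 4 ages, measured with Xenium, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The values are counts of transcripts per feature and cell, whole numbers without normalization, as the authors deposited them in 1 sparse matrix per sample, per the file headers. The submitters' processing notes name Seurat, with neither version nor role. The software that decoded transcripts and drew cell boundaries, any filter applied before deposit and the genome build are not given in the sources used here. Each matrix lists 541 features: 347 genes, 27 negative control probes, 41 negative control codewords, 125 unassigned codewords and 1 deprecated codeword. The 194 control features were left out of library sizes and tests, and their share is given with the depth. Positions of cells in the section were not used here, so that no layer or region was assigned by place. Genes are named by the symbols that the feature tables pair with Ensembl identifiers, for example Fezf2 with ENSMUSG00000021743, Bcl11b with ENSMUSG00000048251, Satb2 with ENSMUSG00000038331, Tle4 with ENSMUSG00000024642, Foxp2 with ENSMUSG00000029563, Tbr1 with ENSMUSG00000035033, Ccn2 with ENSMUSG00000019997 and Cplx3 with ENSMUSG00000039714. Because transcripts are assigned to cells by their boundaries, a cell's count can hold transcripts of its neighbours, and markers of other cell types are reported inside each class of cells.

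Sections held 6139452–30145585 gene transcripts, and the mean negative control probe had 0.0868–0.386% of the mean gene's count. Replicates of a group were compared by a chi-square test of their counts, which gave 130.8–2047 per degree of freedom over 346, so that no pair was 1 library deposited in duplicate. For whole sections, counts of all cells were summed per sample. For classes of cells, counts were summed per sample over the cells of the class with at least 20 transcripts, 1669935 cells in all, and a sample entered with at least 200 such cells. Sums were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Ages were compared in a model with sex as a covariate, in 1 fit of all samples, or of the E15.5, E18.5 and P1 samples for the 4 classes compared between P1 and E15.5. Sexes were compared with age as a covariate, and the variation of the sex difference between ages was tested as an interaction in a model of 8 groups. Fitted log2 changes come with standard errors, and levels are CPM, counts per 1000000 gene transcripts, with a prior count of 2 where log2 values of single samples were taken.

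Cells were clustered over all samples together, from 4000 cells per sample, on log counts scaled to 100 transcripts per cell, with 30 principal components, a graph of shared neighbours among 15 and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15). All other cells were assigned to the cluster whose mean profile gave their counts the highest multinomial likelihood, and 88.0% of the drawn cells fell into their own cluster this way. This gave 32 clusters, and 23 sub-clusters of excitatory cells from 3000 cells per sample. A cluster's leading genes were its 10 highest by fold over the other cells, with 5 transcripts per 10000 added to both levels. A cluster was named only with at least 3 fixed markers of a class among these and no other class with more. Cortical excitatory clusters needed 2 pan cortical excitatory markers among their leading genes, a condition set after the data were seen. It kept out cluster 1, led by Gucy1a1, Syt6 and Penk, which held 0.169 and 0.175% of male and female cells at E12.5, 5.13 and 4.56% at E15.5, 10.4 and 11.5% at E18.5 and 22.0 and 22.1% at P1. Sub-clusters 5, 16 and 18, led by markers of radial glia, oligodendrocytes and endothelium, were taken out of the excitatory class, 37445 cells in all. The corticothalamic-like class came from sub-clusters 2 and 8, the subplate-like class from sub-cluster 14. No doublet caller was run, since merged neighbours in a section are not droplet doublets, and the 1% of cells with the most transcripts was left out as an alternative.

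Before the data were examined, 25 gene lists, the cell type markers, 17 gene pairs, the models and the rule for named genes were fixed. Per contrast, the rule takes the 7 largest rises and the 7 largest falls among genes past the threshold. Their mean count per cell in the higher group had to exceed that of the highest negative control probe, and the samples of both groups could not overlap. Per list described it adds up to 4 members, the 2 with the smallest adjusted p and the 2 with the highest mean level. The sex-linked list (0 of 6 genes measured) and the lists of claustrum, intermediate progenitors, proliferation, choroid plexus and ependyma, and peripheral neurons, each with under 3 members measured, were not tested, and the other 19 were. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, against all other genes tested, and again with an estimated correlation. None of the 11 calls among 227 tests of lists held with the estimated correlation.

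Co-detection was computed in excitatory cells thinned to 50 transcripts, leaving out shallower cells, which kept 94.3–96.8% of the class per sample at E15.5, 95.3–97.4% at E18.5, 77.0–98.3% at P1 and 44.3–98.6% at E12.5. Of 17 pairs 16 had both genes in the panel, and 12 had at least 20 cells expected with both in every tested sample. Ages were compared with the exact two-sided permutation test over 70 splits, adjusted over 24 tests.

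The procedures were tested on simulated data with 200 of 347 genes changed, in 5 runs each. For whole sections between E15.5 and E18.5, 73.4% of 1.5-fold and 95.8% of 2-fold changes were recovered, and 2.53% of calls were false. For excitatory cells in the same step these were 46.8%, 91.4% and 1.57%. A planted list of 10 genes was called in 5 of 5 runs with either correlation, and of 90 random lists 1 was called in excitatory cells at the preset correlation and 0 otherwise. In the simulated co-detection data all 6 changed pairs reached the smallest p, and 0 of 24 tests passed after adjustment.

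Other settings fixed beforehand were DESeq2 1.42.0, no TMM factors, the number of cells as library size, no gene filter, only genes above the highest negative control probe, cells with at least 20 transcripts (sections) or 40 (classes), a Leiden resolution of 1.5, another subsample, the 1% of cells with the most transcripts left out, no covariate, whole-brain sections only, the replicate number as a block, each sample left out in turn, camera with an estimated correlation, fry, and for pairs thinning to 100 transcripts, no thinning and at least 2 transcripts of each gene. Alternatives added after the data were seen left out libraries of low depth, both P1 males, both E12.5 females, clusters of tissue outside the brain, excitatory sub-clusters with more leading markers of another class (17, 19, 20 and 23), or genes of other cell types, or set other library sizes for the count of genes of other cell types. Figures were drawn with matplotlib 3.10.9.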

Results

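Transcripts of a fixed panel of 347 genes were counted in single cells of tissue sections with Xenium, an imaging assay that decodes fluorescent probe signals in place and assigns them to cells. The sections came from formalin-fixed, paraffin-embedded tissue of wild-type mice at 3 embryonic ages, E12.5, E15.5 and E18.5 (days of gestation), and at postnatal day 1 (P1). Each age had 2 male and 2 female samples, 16 in all, and the series is about the deep excitatory neurons of the developing neocortex. E12.5 sections held whole embryos and later ones whole brains, with ever fewer cells of fibroblast or outside-brain clusters. Age and tissue thus change together in every step. Sections held 77076–124103 cells. Gene transcripts per section came to 6139452–15375628 at E12.5, 13589253–18270879 at E15.5, 10281198–20231857 at E18.5 and 18823384–30145585 at P1. The median cell held 61–222 transcripts and 30–74 genes, and the shallowest section, the first E12.5 female, had a median of 61. Control features took 0.0799–0.13% of all transcripts, and 274–338 genes per section lay above its highest negative control probe. Levels are given as mean ± SD CPM, a gene's counts per 1000000 gene transcripts after scaling by TMM factors (n = 4 samples per age), and log2 changes as the fitted value ± its standard error. P-values measure the spread between these samples, since nothing in the labels says that they came from separate animals.

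Sums of whole sections were first compared between E12.5 and E15.5. Hs3st2, which encodes a heparan sulfate sulfotransferase, rose from 53.7 ± 12.1 to 775 ± 30.5 CPM (SD, n = 4), a log2 change of 3.86 ± 0.16. Sla, an adaptor of Src family kinases, rose from 118 ± 28.9 to 1227 ± 33.4 CPM (log2 change 3.37 ± 0.23). Camk2b, a kinase subunit of synapses, rose from 349.7 ± 26.3 to 3403 ± 299.6 CPM (log2 change 3.28 ± 0.11). Of genes of striatal projection neurons, Drd1 rose from 24.9 ± 3.90 to 256 ± 8.47 CPM (log2 change 3.37 ± 0.21), and Ppp1r1b from 85.4 ± 26.4 to 770.3 ± 47.7 CPM (3.18 ± 0.25). Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 49.8 ± 21.7 to 1027 ± 123 CPM (log2 change 4.38 ± 0.38). Myl4, a myosin light chain gene, rose from 67.4 ± 6.04 to 947 ± 663 CPM (log2 change 3.71 ± 0.57). Among the largest falls were the secreted enhancers of Wnt signalling: Rspo2 fell from 2304 ± 409 to 206 ± 38.6 CPM (log2 change -3.49 ± 0.29), and Rspo1 from 1695 ± 314 to 219 ± 63.2 CPM (-2.95 ± 0.27). Of transcriptional regulators, Mecom fell from 4399.9 ± 1599 to 432 ± 72.1 CPM (log2 change -3.33 ± 0.21), and Eya4 from 7273 ± 2029 to 839 ± 157 CPM (-3.10 ± 0.26). Ebf3, a regulator of early neurons, fell from 8828 ± 635 to 1073 ± 249 CPM (log2 change -3.04 ± 0.46). Erbb3, a neuregulin receptor of Schwann cell precursors, fell from 2680.0 ± 1145 to 347 ± 98.5 CPM (log2 change -2.94 ± 0.34), and Pthlh, parathyroid hormone-like hormone, from 810.3 ± 178 to 125 ± 21.6 CPM (-2.69 ± 0.19).

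Of the 7 pan cortical excitatory genes measured, 7 rose (7 passing adjusted over the list alone, camera adjusted p = 0.0242, and adjusted p = 0.641 with an estimated correlation), among them Neurod6 (log2 change 2.92 ± 0.38), Tbr1 (log2 change 1.44 ± 0.0971) and Satb2 (log2 change 0.71 ± 0.19). Of 8 corticothalamic genes, 7 rose and 1 fell (8 passing adjusted over the list alone, camera adjusted p = 0.0619). Hs3st4 (log2 change 2.03 ± 0.0939) and Foxp2 (0.63 ± 0.16) rose, and Tle4 (-0.47 ± 0.0924) fell, a call lost without TMM factors. Of 6 radial glia genes, 5 fell and 1 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.149), including Nes (log2 change -1.34 ± 0.12), an intermediate filament gene of progenitors, Sox2 (log2 change -0.97 ± 0.10) and Gli3 (log2 change -1.55 ± 0.12). Among 7 interneuron genes, 3 rose, 2 fell and 2 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.955): the peptide gene Sst (log2 change 1.47 ± 0.24) rose, Gad2 (log2 change -0.22 ± 0.14) did not pass, and Gad1 (log2 change 0.52 ± 0.14) had the other sign without cells of tissue outside the brain (log2 change -0.0697). Of 5 striatal genes, 3 rose, 1 fell and 1 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.268). Meis2 (log2 change 0.19 ± 0.14) did not pass. Of 8 oligodendrocyte lineage genes, 3 fell and 5 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.441), with Pdgfra (log2 change -2.52 ± 0.20) and Sox10 (log2 change -2.16 ± 0.23), which neural crest and mesenchyme also express. Of 12 fibroblast and mesenchyme genes, 4 rose, 6 fell and 2 did not pass (10 passing adjusted over the list alone, camera adjusted p = 0.955), with a rise of Fmod (log2 change 1.19 ± 0.16) and falls of Igf2 (log2 change -1.12 ± 0.24) and Fn1 (log2 change -1.58 ± 0.24).

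In all, 248 of 347 genes tested, 125 higher and 123 lower at E15.5, passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and the genes named as passing had edgeR adjusted p-values of at most 0.00479. Scaled per cell, that is with the number of cells as library size, the split was 114 higher and 68 lower, and without TMM factors 160 higher and 92 lower. Calls ended per cell for Tle4 and Gad1. Cells of clusters led by fibroblast genes or by genes of tissue outside the brain made up 43.4–47.2% of cells at E12.5 and 14.3–23.7% at E15.5.

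The next step compared whole sections at E15.5 and E18.5. Among the largest rises were 2 genes of astrocytes. Gfap, the intermediate filament gene, rose from 30.2 ± 5.71 to 318 ± 26.2 CPM (log2 change 3.40 ± 0.20). Aqp4, the water channel gene, rose from 36.4 ± 8.57 to 281 ± 40.6 CPM (log2 change 2.94 ± 0.21). Nrgn, which encodes neurogranin, rose from 801 ± 68.3 to 4345 ± 777 CPM (log2 change 2.45 ± 0.22). Nwd2 rose from 285 ± 37.7 to 1529 ± 112 CPM (log2 change 2.43 ± 0.30). Car4, a carbonic anhydrase gene, rose from 71.1 ± 5.39 to 279 ± 12.3 CPM (log2 change 1.97 ± 0.12), and the log2 change was 1.97 ± 0.22 for Rprml and 2.12 ± 0.18 for Ly6a. Mki67, a gene of dividing cells, fell from 12138 ± 975 to 3107 ± 368 CPM (log2 change -1.96 ± 0.14). Pax6, a radial glia gene, fell from 3682 ± 327 to 1158 ± 209 CPM (log2 change -1.67 ± 0.24). With Dkk3 and Rorb it led cluster 23, of 15873 cells at E15.5 and 13 at E18.5. Wnt8b, a Wnt ligand of the cortical hem, fell from 202 ± 37.4 to 38.5 ± 62.3 CPM (log2 change -2.51 ± 0.82), a change of -4.92 without the first E18.5 female. Erbb3 fell from 347 ± 98.5 to 66.2 ± 29.2 CPM (log2 change -2.37 ± 0.33), and Eya4 from 839 ± 157 to 254 ± 86.1 CPM (-1.72 ± 0.24). Ror1 fell from 700.4 ± 94.3 to 210.2 ± 52.0 CPM (log2 change -1.73 ± 0.16). Hapln1, a link protein gene of cartilage and of perineuronal nets, fell from 1106 ± 355 to 312 ± 148 CPM (log2 change -1.84 ± 0.32), and had the other sign without cells of tissue outside the brain (1.19).

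Of 6 radial glia genes, 5 fell and 1 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.0665), including Gli3 (log2 change -1.58 ± 0.12) and Nes (log2 change -1.41 ± 0.12). Of 9 neuronal maturation genes, 5 rose, 2 fell and 2 did not pass (7 passing adjusted over the list alone, camera adjusted p = 0.252), with a rise of Rims3 (log2 change 1.17 ± 0.13), a gene of the presynaptic active zone. Of 5 genes of Cajal-Retzius cells, early neurons of the marginal zone, 4 fell and 1 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.293). Trp73 (log2 change -1.10 ± 0.15) and Lhx1 (-1.32 ± 0.28) fell and Reln (0.29 ± 0.15) did not pass. Of 5 astrocyte genes, 3 rose and 2 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.119). Of 8 oligodendrocyte lineage genes, 2 rose, 3 fell and 3 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.941), with a median log2 change of -0.15, a mean of 0.19 and a camera direction of up; Gpr17 (log2 change 1.72 ± 0.15) and Olig1 (log2 change 1.72 ± 0.15), genes of its precursors, rose, and Pdgfra (log2 change -0.56 ± 0.19) fell, but rose without tissue outside the brain (0.60, adjusted p = 0.0045). Of 13 endothelial genes, 3 rose, 6 fell and 4 did not pass (10 passing adjusted over the list alone, camera adjusted p = 0.941), with a median log2 change of -0.31, a mean of 0.18 and a camera direction of down; Cldn5 (log2 change 0.13 ± 0.20), a tight junction gene, did not pass. Of 5 mural cell genes, 1 rose, 3 fell and 1 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.577). The smooth muscle actin gene Acta2 fell (log2 change -0.77 ± 0.19). Gucy1a1 rose (1.15 ± 0.15), but also leads cluster 1, of 22248 cells at E15.5 and 47030 at E18.5. Of 12 fibroblast and mesenchyme genes, 7 fell and 5 did not pass (7 passing adjusted over the list alone, camera adjusted p = 0.0665), including the collagen gene Col1a1 (log2 change -1.53 ± 0.28) and Igf2 (log2 change -1.18 ± 0.24).

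The test called 226 of 347 genes tested, 114 higher and 112 lower at E18.5, and the genes named as passing had edgeR adjusted p-values of at most 0.0181. Per cell, 148 genes passed, 95 higher and 53 lower. Calls ended per cell for Acta2 and Pdgfra. Cells of fibroblast or outside-brain clusters fell to 3.37–10.5% of cells at E18.5.

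The last step compared whole sections at E18.5 and P1. Lamp5, a membrane protein gene of neurons, rose from 53.6 ± 9.75 to 221 ± 28.5 CPM (log2 change 2.03 ± 0.22). Cplx3, a complexin gene of subplate and of some interneurons, rose from 24.2 ± 4.47 to 75.8 ± 19.2 CPM (log2 change 1.65 ± 0.25). Itpka, an inositol trisphosphate kinase gene of dendritic spines, rose from 239.8 ± 37.2 to 641 ± 49.8 CPM (log2 change 1.42 ± 0.15). Aqp4 rose from 281 ± 40.6 to 643 ± 45.0 CPM (log2 change 1.19 ± 0.19), and Trbc2 from 26.0 ± 4.92 to 60.9 ± 16.9 CPM (1.22 ± 0.21). Pde11a rose from 104 ± 45.7 to 271 ± 75.2 CPM (log2 change 1.45 ± 0.34), and Unc13c from 45.1 ± 15.7 to 111 ± 34.6 CPM (1.34 ± 0.37). Both lost the call when the P1 males were left out (log2 changes 0.94 and 0.65). Spp1 fell from 1824 ± 953 to 199 ± 38.8 CPM (log2 change -3.16 ± 0.35), and Col1a1 from 5039.8 ± 1766 to 819 ± 45.4 CPM (-2.63 ± 0.29). Dcn, which encodes the matrix proteoglycan decorin, fell from 2317 ± 851 to 555 ± 155 CPM (log2 change -2.07 ± 0.29). Igf2 fell from 9998 ± 4101 to 2659 ± 376 CPM (log2 change -1.92 ± 0.24), and Lhx9 from 145 ± 74.9 to 38.9 ± 7.85 CPM (-1.89 ± 0.37).

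Of 9 neuronal maturation genes, 3 rose, 1 fell and 5 did not pass (6 passing adjusted over the list alone, camera adjusted p = 0.0887). Nrn1 (log2 change -1.47 ± 0.30), the gene of the neurite growth factor neuritin, fell, and Rims3 (0.0666 ± 0.13) did not pass. Of 5 striatal genes, 2 rose and 3 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.0887), with a rise of Drd1 (log2 change 1.02 ± 0.19). Of 5 Cajal-Retzius genes, 3 fell and 2 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.155), including Lhx1 (log2 change -1.78 ± 0.28). Of 5 astrocyte genes, 2 rose and 3 did not pass (2 passing adjusted over the list alone, camera adjusted p = 0.0887), with a rise of Gfap (log2 change 1.07 ± 0.18). Of 8 microglia and macrophage genes, 3 fell and 5 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.309). Spi1 (log2 change -0.82 ± 0.18), their lineage transcription factor gene, and Cd68 (-0.56 ± 0.0895), a lysosomal gene, fell. Of 13 endothelial genes, 1 rose, 6 fell and 6 did not pass (8 passing adjusted over the list alone, camera adjusted p = 0.0887), with a fall of the receptor gene Acvrl1 (log2 change -0.97 ± 0.11) and a rise of Car4 (log2 change 0.75 ± 0.12). Of 12 fibroblast and mesenchyme genes, 1 rose, 7 fell and 4 did not pass (8 passing adjusted over the list alone, camera adjusted p = 0.01, and adjusted p = 0.401 with an estimated correlation), including Fn1 (log2 change -1.10 ± 0.24).

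The test called 128 of 347 genes tested, 54 higher and 74 lower at P1. The genes named as passing had edgeR adjusted p-values of at most 0.0115, except for Ppp1r1b at 0.0471. Without both P1 males 61 genes passed, and per cell 100, 85 higher and 15 lower. Calls were lost per cell for Acvrl1, Cd68, Nrn1, Spi1 and Fn1, and without both P1 males for Nrn1, Spi1, Pde11a and Unc13c, and without cells of tissue outside the brain for Fn1. Cells of fibroblast or outside-brain clusters were 1.07–1.30% of cells at P1.

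Males and females of all ages were compared with age as a covariate, and none of the 6 sex-linked genes fixed beforehand was in the panel. In whole sections, edgeR called 0 of 347 genes between the sexes, with 12 at an unadjusted p under 0.05 and 0 called by DESeq2. In cortical excitatory neuron-like cells, described next, edgeR called 0 of 347, with 7 at an unadjusted p under 0.05 and 0 called by DESeq2. Of the 8 microglia and macrophage genes 0 passed in whole sections, and 0 when adjusted over the list alone, while camera called the list as a whole, higher in males (median log2 difference 0.11, adjusted p = 0.0128, and adjusted p = 0.087 with an estimated correlation). The sex difference varied between ages, by edgeR's test of the interaction, for 31 genes in excitatory cells and for 1 in whole sections, Neurod6 (edgeR adjusted p = 0.0352), a transcription factor gene of cortical neurons. Id2, an inhibitor of basic helix-loop-helix transcription factors, varied this way (edgeR adjusted p = 0.00145). It was at 4295 and 3592 CPM in the P1 males against 9984 and 9159 CPM in the P1 females. At E12.5 it was at 5130.2 and 8293 CPM in the males against 2745 and 2852 CPM in the females. Mapt, which encodes the microtubule protein tau, went the other way (edgeR adjusted p = 0.00145). It was at 33415 and 40424 CPM in the P1 males against 18592 and 19038 CPM in the P1 females. At E12.5 it was at 7636 and 6746 CPM in the males against 17151 and 16072 CPM in the females. These genes were chosen after their values were seen. Both P1 males also stood apart in how their excitatory cells clustered, holding 7928 and 11253 of the 19264 cells of excitatory sub-cluster 10. Its median was 122 transcripts in the cells drawn. At E12.5, sub-cluster 20, with a median of 49 transcripts in the cells drawn, held 1500 and 628 cells of the females and 30 and 4 of the males.

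**Figure D1:**
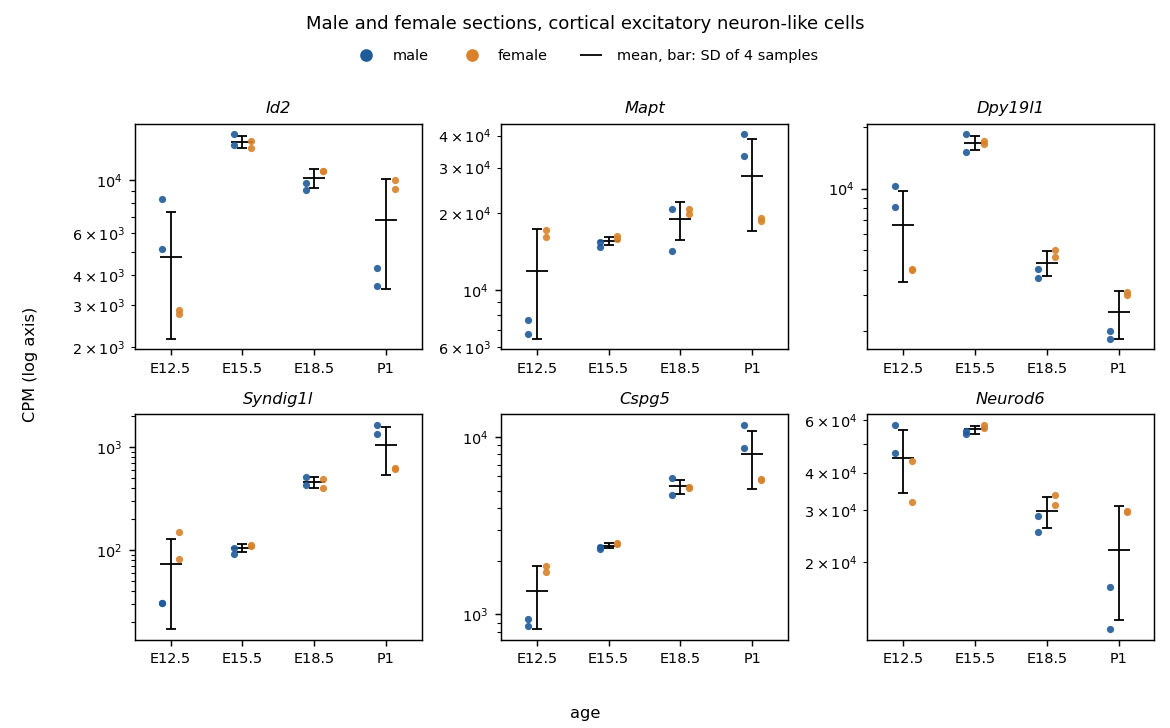
Level (CPM, log axis) of Id2, Mapt, Dpy19l1, Syndig1l, Cspg5 and Neurod6 in cortical excitatory neuron-like cells at each age, with a point per sample (male blue, female orange) and the mean and SD of 4 samples. Id2 lay at 4295 and 3592 CPM in the P1 males, below both P1 females, and at E12.5 both males lay above both females.

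Cortical excitatory neuron-like cells were then taken by clustering, as the cells closest to the neocortical neurons that the series is about. The class held 2348–31430 cells and 119335–8814100 gene transcripts per sample, from 5 clusters. Of these, the largest at E15.5 was cluster 6, led by Nrn1, Neurod1 and Sstr2 (51896 cells), and at E18.5 and P1 cluster 3, led by Satb2, Bhlhe22 and Nwd2 (53015 and 67925 cells), counted before any sub-clusters were taken out. At E12.5 nearly all of its 13184 cells lay in 5 sub-clusters, numbered 17, 19, 20, 21 and 23, whose leading genes, such as Nes, Mki67, Eomes and Lhx9, are those of progenitors or of other neurons.

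Excitatory cells were compared between E12.5 and E15.5 first. Sla rose from 213 ± 96.6 to 4640.1 ± 127 CPM (log2 change 4.36 ± 0.27), and Kctd12 from 578 ± 194 to 8307 ± 181 CPM (3.82 ± 0.20). Necab1, a calcium-binding protein gene, rose from 44.5 ± 9.17 to 2375 ± 67.8 CPM (log2 change 5.80 ± 0.23). Htr1f, a serotonin receptor gene, rose from 31.9 ± 24.3 to 347 ± 28.7 CPM (log2 change 3.68 ± 0.36). Rxfp1, a relaxin receptor gene, rose from 8.12 ± 8.26 to 85.3 ± 6.05 CPM, the E12.5 level not being above that of the mean negative control probe in these cells (9.717 CPM), so that no log2 change is given. Pdzd2 rose from 63.3 ± 15.6 to 731 ± 33.7 CPM (log2 change 3.61 ± 0.28). Nr2f2, a nuclear receptor gene of caudal and ventral forebrain, fell from 10334 ± 6575 to 650.3 ± 75.6 CPM (log2 change -3.94 ± 0.56). Lhx9, a transcription factor gene of the early diencephalon and of eminential neurons, fell from 7696 ± 938 to 599.6 ± 127 CPM (log2 change -3.67 ± 0.38). Cntnap2 fell from 25566 ± 4152 to 2352 ± 122 CPM (log2 change -3.43 ± 0.18), and Lamp5 from 122 ± 68.4 to 8.42 ± 0.995 CPM (-3.95 ± 0.32). Tmem163 fell from 2961 ± 1356 to 238 ± 21.3 CPM (log2 change -3.64 ± 0.28), and Unc13c from 212 ± 92.0 to 18.1 ± 4.34 CPM (-3.51 ± 0.50). Of 8 corticothalamic genes, 6 rose, 1 fell and 1 did not pass (8 passing adjusted over the list alone, camera adjusted p = 0.0697). Hs3st4 (log2 change 2.20 ± 0.19) and Tbr1 (log2 change -0.90 ± 0.17) lost their calls without sub-clusters 17, 19, 20 and 23 (log2 changes 0.36 and -0.25), which had more leading markers of another class. Sub-cluster 21, led by Lhx9, then gave 1935 of the 2054 E12.5 cells left. Of 6 subplate and layer 6b genes, 3 rose, 1 fell and 2 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.595). The potassium channel subunit gene Kcnab1 (log2 change 2.77 ± 0.23) rose and the neurexophilin gene Nxph4 (-1.83 ± 0.17) fell. Nr4a2, a nuclear receptor gene of subplate neurons, rose from 1151 ± 428 to 2336 ± 201 CPM (log2 change 1.01 ± 0.29), and had the other sign in that setting (-0.94).

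Of 5 layer 5 genes, 1 rose, 1 fell and 3 did not pass (2 passing adjusted over the list alone, camera adjusted p = 0.888), with a median log2 change of -0.14, a mean of 0.04 and a camera direction of down; Fezf2 (log2 change 1.21 ± 0.28) rose, a call lost without both E12.5 females (0.63), and Bcl11b (log2 change 0.0533 ± 0.21) did not pass but was a fall past the threshold without them (-0.49, adjusted p = 0.022). Of 7 upper layer and callosal genes, 5 rose and 2 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.0496, and adjusted p = 0.278 with an estimated correlation). Satb2 (log2 change 2.45 ± 0.22), Rorb (2.05 ± 0.16) and Rasgrf2 (2.12 ± 0.18) rose and Cux1 (-0.0776 ± 0.14) did not pass. Of 6 radial glia genes, 6 fell (6 passing adjusted over the list alone, camera adjusted p = 0.0438, and adjusted p = 0.345 with an estimated correlation), including Nes (log2 change -2.29 ± 0.19) and Sox2 (log2 change -1.35 ± 0.16). Of 5 Cajal-Retzius genes, 5 fell (5 passing adjusted over the list alone, camera adjusted p = 0.0604), including Reln (log2 change -1.51 ± 0.16) and Ebf3 (log2 change -3.17 ± 0.31). Of 3 subcortical glutamatergic genes, 1 rose and 2 fell (3 passing adjusted over the list alone, camera adjusted p = 0.465), with a fall of the glutamate transporter gene Slc17a6 (log2 change -1.80 ± 0.21). Of 12 fibroblast and mesenchyme genes, 4 rose and 8 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.268), with Adamts2 (log2 change 4.20 ± 0.19) and Fn1 (log2 change 1.14 ± 0.22), which were also among the leading genes of excitatory sub-clusters, 1 and 3 for Adamts2 and 1 and 6 for Fn1. The test called 200 of 347 genes tested, 104 higher and 96 lower at E15.5, and the genes named as passing had edgeR adjusted p-values of at most 0.00684. Per cell, the split was 110 higher and 43 lower, and without TMM factors 136 higher and 77 lower. Calls did not hold per cell for Sox2 and Tbr1. Without sub-clusters 17, 19, 20 and 23, which left 288–631 cells per E12.5 sample, nearly all of sub-cluster 21, 196 genes passed, 148 of them among the 200.

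Excitatory cells at E18.5 were then set against those at E15.5. Nwd2 rose from 270.3 ± 51.6 to 3614 ± 494 CPM (log2 change 3.74 ± 0.24), and Nrgn from 1567 ± 178 to 8835 ± 1540.2 CPM (2.50 ± 0.20). Rasgrf2, a guanine nucleotide exchange factor gene, rose from 199.7 ± 11.3 to 1441 ± 184 CPM (log2 change 2.85 ± 0.16). These 3 are among the 10 genes that lead cluster 3. Ccn2, a matricellular protein gene that marks subplate neurons in the cortex, rose from 87.9 ± 17.0 to 549 ± 28.9 CPM (log2 change 2.64 ± 0.22). Dkk3 rose from 265 ± 25.8 to 1342 ± 253 CPM (log2 change 2.34 ± 0.24), and Gfap from 6.77 ± 1.60 to 50.6 ± 12.6 CPM (2.89 ± 0.27), the latter an astrocyte gene. Lhx9 fell from 599.6 ± 127 to 75.8 ± 57.5 CPM (log2 change -3.01 ± 0.37), and Pde11a from 119 ± 11.6 to 23.7 ± 9.72 CPM (-2.32 ± 0.29). Dpy19l1, a gene of migrating neurons, fell from 16794 ± 1377 to 4319 ± 599 CPM (log2 change -1.96 ± 0.28). Eomes, the T-box gene of intermediate progenitors, fell from 759 ± 101 to 201 ± 156 CPM (log2 change -1.95 ± 0.39). Nes fell from 4356 ± 338 to 1179.6 ± 211 CPM (log2 change -1.88 ± 0.19), and Pdzrn3 from 3087 ± 255 to 883 ± 255 CPM (-1.81 ± 0.26). Of 6 subplate and layer 6b genes, 4 rose, 1 fell and 1 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.16), with a rise of Cplx3 (log2 change 2.19 ± 0.20). Nr4a2 (log2 change -0.16 ± 0.29) did not pass, and Nxph4 (-0.95 ± 0.16) fell. Of 8 corticothalamic genes, 4 fell and 4 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.136). The falls of Tle4 (log2 change -0.59 ± 0.15) and Foxp2 (-0.56 ± 0.15) were lost without TMM factors. Of 5 layer 5 genes, 2 fell and 3 did not pass (2 passing adjusted over the list alone, camera adjusted p = 0.592), with a median log2 change of 0.21 and a mean of -0.38. Fezf2 (log2 change -1.64 ± 0.29) and Bcl11b (-1.40 ± 0.22), transcription factor genes of subcerebral neurons, fell.

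**Figure D2:**
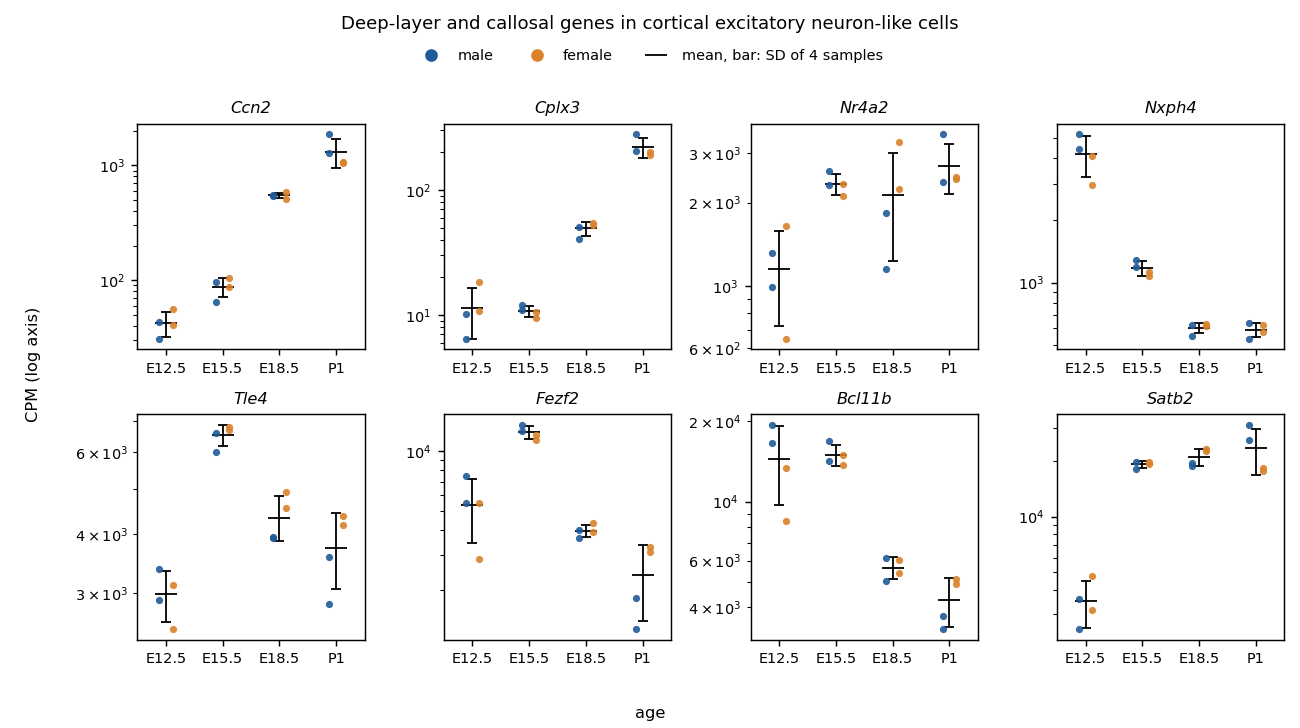
Level (CPM, log axis) of 8 deep-layer and callosal genes in cortical excitatory neuron-like cells at each age, with a point per sample (male blue, female orange) and the mean and SD of 4 samples. Ccn2 went from 87.9 ± 17.0 to 549 ± 28.9 CPM between E15.5 and E18.5, and Fezf2 from 12377 ± 937 to 3975 ± 280.3 CPM.

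Of 6 newborn neuron genes, 3 fell and 3 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.135). Neurod1 (log2 change -1.15 ± 0.25), Dcx (-0.65 ± 0.15), the gene of the microtubule protein doublecortin, and Sox11 (-0.82 ± 0.23) fell. Of 9 neuronal maturation genes, 5 rose, 1 fell and 3 did not pass (6 passing adjusted over the list alone, camera adjusted p = 0.16), with a rise of Rims3 (log2 change 1.45 ± 0.22) and a fall of Nrn1 (log2 change -1.43 ± 0.26). Of 4 activity-regulated genes, 3 rose and 1 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.152), including Bhlhe40 (log2 change 1.87 ± 0.28). Genes of other cell types were measured inside these neuron-like cells too: of 5 astrocyte genes, 3 rose and 2 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.135), such as Aqp4 from 4.38 ± 1.83 to 24.7 ± 4.78 CPM. Of 8 oligodendrocyte lineage genes, 5 rose and 3 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.16), such as Gpr17 (log2 change 1.30 ± 0.23). Of 12 fibroblast and mesenchyme genes, 4 fell and 8 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.152), such as Fn1 (log2 change -1.41 ± 0.22). The test called 163 of 347 genes tested, 93 higher and 70 lower at E18.5, and the genes named as passing had edgeR adjusted p-values of at most 0.00747. Per cell, 96 genes passed, 79 higher and 17 lower, and without TMM factors the split was 133 higher and 44 lower. Calls were lost per cell for Bcl11b, Nxph4, Nrn1, Neurod1, Dcx, Tle4, Foxp2 and Sox11.

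Between E18.5 and P1, the subplate genes Cplx3 and Ccn2 rose again in excitatory cells. Cplx3 rose from 49.4 ± 6.20 to 219 ± 39.8 CPM (log2 change 2.15 ± 0.19), and Lamp5 from 16.7 ± 2.71 to 49.0 ± 6.65 CPM (1.55 ± 0.27). Trbc2 rose from 18.8 ± 6.40 to 129 ± 56.9 CPM (log2 change 2.76 ± 0.39), and Gm19410 from 121 ± 4.09 to 395 ± 154 CPM (1.69 ± 0.30). The hyaluronan receptor gene Cd44 (log2 change 3.11 ± 0.34) was among the largest rises too. Of astrocyte genes, Aqp4 rose from 24.7 ± 4.78 to 88.8 ± 7.99 CPM (log2 change 1.84 ± 0.29), and Acsbg1 from 112 ± 19.5 to 323 ± 115 CPM (1.51 ± 0.24). Col1a1 fell from 1206 ± 609 to 24.5 ± 3.82 CPM (log2 change -5.61 ± 0.46), and Spp1 from 163 ± 47.0 to 21.7 ± 3.87 CPM (-2.89 ± 0.23). Igf2 fell from 783 ± 291 to 144 ± 50.2 CPM (log2 change -2.43 ± 0.34), and Pax6 from 222 ± 58.8 to 83.2 ± 28.6 CPM (-1.41 ± 0.32). Nhlh2 fell from 317 ± 89.7 to 127 ± 17.5 CPM (log2 change -1.32 ± 0.23), and Nrn1 from 2322 ± 641 to 965 ± 99.1 CPM (-1.27 ± 0.26). Of 6 subplate and layer 6b genes, 3 rose and 3 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.0285, and adjusted p = 0.13 with an estimated correlation). Ccn2 (log2 change 1.26 ± 0.21) rose, and Nr4a2 (0.37 ± 0.29) and Nxph4 (-0.0336 ± 0.16) did not pass. Of 9 neuronal maturation genes, 3 rose, 1 fell and 5 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.0805), with a rise of Nrgn (log2 change 0.79 ± 0.19). Of 6 newborn neuron genes, 2 fell and 4 did not pass (2 passing adjusted over the list alone, camera adjusted p = 0.382), and of 4 activity-regulated genes, 2 rose and 2 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.0909). Of 5 astrocyte genes, 3 rose and 2 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.0596). Of 8 microglia and macrophage genes, 5 fell and 3 did not pass (7 passing adjusted over the list alone, camera adjusted p = 0.00303, and adjusted p = 0.0911 with an estimated correlation), such as Cd68 (log2 change -0.97 ± 0.17). Of 13 endothelial genes, 1 rose, 6 fell and 6 did not pass (8 passing adjusted over the list alone, camera adjusted p = 0.165), such as Emcn (log2 change -1.05 ± 0.27), and of 12 fibroblast and mesenchyme genes, 4 fell and 8 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.0285, and adjusted p = 0.333 with an estimated correlation).

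The test called 95 of 347 genes tested, 47 higher and 48 lower at P1, and the genes named as passing had edgeR adjusted p-values of at most 0.0101. Without both P1 males 40 genes passed, 36 of them among the 95, and 57 without the first P1 male. Per cell, 50 passed, 43 higher and 7 lower. Calls did not hold per cell for Nhlh2, Cd68, Nrn1, Pax6 and Emcn, and without both P1 males for Pax6 and Emcn.

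Within corticothalamic-like cells, the deep-layer neurons that project to the thalamus, P1 was compared with E15.5 (4497–5807 cells and 646980–1424061 gene transcripts per sample). Sub-cluster 8 held 21234 of its cells at E15.5, and sub-cluster 2 held 18993 at P1. Nts, the neurotensin gene, rose from 128 ± 57.0 to 6139 ± 2568 CPM (log2 change 5.92 ± 0.82). Syt6, a synaptotagmin gene, rose from 6550.1 ± 706 to 14353 ± 2046 CPM (log2 change 1.13 ± 0.13). These 2 are among the 10 genes that lead sub-cluster 2, and Fezf2 is among those that lead sub-cluster 8. Fezf2 fell from 23135 ± 1694 to 5810.0 ± 2621 CPM (log2 change -2.08 ± 0.21). Cplx3 rose from 10.9 ± 3.98 to 241 ± 59.0 CPM (log2 change 4.47 ± 0.29), and Cd44 from 24.9 ± 8.04 to 761 ± 183 CPM (4.90 ± 0.24). Trbc2 rose from 8.73 ± 5.96 to 464 ± 187 CPM (log2 change 5.67 ± 0.41), and Dkk3 from 168 ± 24.2 to 5079.5 ± 1229 CPM (4.91 ± 0.19). Of astrocyte genes, Aqp4 rose from 2.01 ± 2.54 to 103 ± 8.41 CPM, and Acsbg1 from 19.1 ± 8.12 to 418 ± 127 CPM. Col1a1 fell from 1986 ± 796 to 22.2 ± 5.82 CPM (log2 change -6.49 ± 0.47), and Igf2 from 1545 ± 450.2 to 137 ± 47.0 CPM (-3.52 ± 0.32). Pde11a fell from 363 ± 56.6 to 28.2 ± 13.1 CPM (log2 change -3.73 ± 0.32), and Nrn1 from 3206 ± 401 to 252 ± 14.8 CPM (-3.67 ± 0.16). Nhlh2 fell from 866 ± 105 to 86.0 ± 26.2 CPM (log2 change -3.35 ± 0.23), and Dpy19l1 from 20124 ± 2321 to 3047 ± 1460.1 CPM (-2.82 ± 0.21). Of 8 corticothalamic genes, 1 rose, 4 fell and 3 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.298). Rprm (log2 change -1.26 ± 0.10), a gene of layer 6 neurons, fell, and Tle4 (log2 change -0.23 ± 0.11), which did not pass, had the other sign per cell (log2 change 0.53). Of 6 subplate and layer 6b genes, 4 rose, 1 fell and 1 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.302). The phosphatase gene Inpp4b (log2 change 1.70 ± 0.19) rose, Nxph4 (log2 change -0.15 ± 0.13), with the other sign in that setting (0.62), did not pass, and Nr4a2 (log2 change -1.27 ± 0.21) fell. Of 5 layer 5 genes, 1 rose and 4 fell (5 passing adjusted over the list alone, camera adjusted p = 0.159), including Bcl11b (log2 change -1.93 ± 0.16).

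Of 7 pan cortical excitatory genes, 1 rose and 6 fell (7 passing adjusted over the list alone, camera adjusted p = 0.055), including Bhlhe22 (log2 change -2.14 ± 0.13) and Neurod6 (log2 change -1.54 ± 0.18). Of 6 newborn neuron genes, 6 fell (6 passing adjusted over the list alone, camera adjusted p = 0.055), including Sox11 (log2 change -1.44 ± 0.12) and Nrep (log2 change -0.70 ± 0.12), the latter at a log2 change of 0.0101 per cell. Of 9 neuronal maturation genes, 5 rose, 2 fell and 2 did not pass (7 passing adjusted over the list alone, camera adjusted p = 0.332), with a rise of Nrgn (log2 change 3.71 ± 0.19) and a fall of the vesicular glutamate transporter gene Slc17a7 (log2 change -0.44 ± 0.14), which had the other sign per cell (0.34). Of 4 astrocyte genes measured in these cells, 3 rose and 1 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.0904), and of 12 fibroblast and mesenchyme genes, 1 rose, 8 fell and 3 did not pass (9 passing adjusted over the list alone, camera adjusted p = 0.055). The test called 255 of 337 genes tested, 135 higher and 120 lower at P1, and the genes named as passing had edgeR adjusted p-values of at most 0.00817. Per cell, the split was 184 higher and 45 lower, and without TMM factors 162 higher and 82 lower. Calls ended per cell for Rprm and Nr4a2.

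Within subplate-like cells, among the first-born neurons beneath the cortical plate, P1 was compared with E15.5 (635–1264 cells and 104603–451294 gene transcripts per sample); sub-cluster 14 alone held the class at both ages. Cplx3 rose from 48.3 ± 12.2 to 3383 ± 651 CPM (log2 change 6.12 ± 0.23), and Ccn2 from 966 ± 325 to 25481 ± 4630.0 CPM (4.70 ± 0.20). Pcp4, a calmodulin-binding protein gene, rose from 1463 ± 241 to 15786 ± 2747 CPM (log2 change 3.43 ± 0.15). Cd44 rose from 16.3 ± 10.8 to 315 ± 93.5 CPM (log2 change 4.24 ± 0.39). The astrocyte gene Aqp4 rose from 1.83 ± 3.66 to 135 ± 43.6 CPM, and Acsbg1 from 19.5 ± 7.69 to 409 ± 126 CPM. Col1a1 fell from 1750.4 ± 765 to 30.9 ± 20.4 CPM (log2 change -5.81 ± 0.55), and Igf2 from 1426 ± 318 to 179 ± 62.1 CPM (-2.99 ± 0.30). Fn1 fell from 1190.1 ± 193 to 248 ± 62.2 CPM (log2 change -2.25 ± 0.23), and Nhlh2 from 2299 ± 247 to 219 ± 68.7 CPM (-3.38 ± 0.21). Lhx9 fell from 267 ± 95.7 to 37.9 ± 8.37 CPM (log2 change -2.82 ± 0.31). Zfp366, an endothelial gene, fell from 139.8 ± 34.0 to 17.0 ± 1.30 CPM (log2 change -2.99 ± 0.39). Of 6 subplate and layer 6b genes, 4 rose and 2 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.0922), the list that names the class. Of 8 corticothalamic genes, 2 rose, 3 fell and 3 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.473). Syt6 (log2 change 1.88 ± 0.23) rose, Rprm (log2 change -1.89 ± 0.12) fell, and Tbr1 (log2 change -0.64 ± 0.0873) and Tle4 (log2 change -0.53 ± 0.0957) had the other sign per cell (log2 changes 0.23 and 0.35). Of 5 layer 5 genes, 1 rose and 4 fell (5 passing adjusted over the list alone, camera adjusted p = 0.271), with a fall of Bcl11b (log2 change -1.05 ± 0.11), a median log2 change of -1.01 and a mean of -0.13.

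Of 6 newborn neuron genes, 5 fell and 1 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.07), including Sox11 (log2 change -1.78 ± 0.0959) and Cd24a (log2 change -1.40 ± 0.14), a surface glycoprotein gene. Of 7 neuronal maturation genes, 5 rose and 2 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.122), including Nrgn (log2 change 2.26 ± 0.17) and Cpne6 (log2 change 1.80 ± 0.18), a copine gene of excitatory neurons. Of 3 activity-regulated genes, 2 rose and 1 did not pass (2 passing adjusted over the list alone, camera adjusted p = 0.282), with a rise of Arc (log2 change 2.17 ± 0.43), which encodes a protein of active synapses. Of 3 astrocyte genes 2 rose, and of 6 oligodendrocyte lineage genes 6 (camera adjusted p = 0.122 and 0.07). Of 5 microglia and macrophage genes 3 fell, and of 8 fibroblast and mesenchyme genes 2 rose and 5 fell (camera adjusted p = 0.122 and 0.193). As many passed adjusted over each list alone. The test called 195 of 288 genes tested, 107 higher and 88 lower at P1, and the genes named as passing had edgeR adjusted p-values of at most 0.000276. Per cell, the split was 181 higher and 21 lower. Calls were lost per cell for Cd24a and Bcl11b.

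Within radial glia-like cells, the neural progenitors of the ventricular zone, P1 was compared with E15.5 (897–13360 cells and 138964–2023000 gene transcripts per sample). The class came from clusters 10, 15 and 22. Cluster 15, led by Eomes, Pax6 and Gli3 with Wnt8b and Rmst, held 23699 cells at E15.5 and 1089 at P1. Cluster 22, led by Rmst and Rfx4 with Rspo1 and Lhx9, held 4281 and 10, and cluster 10, led by Hes5 and Olig2, 24520 and 3071. Gfap rose from 171 ± 34.7 to 3275 ± 453 CPM (log2 change 4.27 ± 0.27). Pdgfra, the receptor gene of oligodendrocyte precursors, rose from 454 ± 30.9 to 3459.7 ± 522 CPM (log2 change 2.92 ± 0.16). Hapln1 rose from 60.3 ± 2.60 to 350.2 ± 112 CPM (log2 change 2.52 ± 0.23), and Spp1 from 176 ± 21.2 to 907 ± 379.6 CPM (2.34 ± 0.30). Ctxn2 rose from 11.5 ± 1.19 to 55.5 ± 19.6 CPM, with an E15.5 level not above the mean probe's (12.41 CPM). Trem2, a microglial receptor gene, rose from 52.0 ± 4.68 to 276 ± 137 CPM (log2 change 2.33 ± 0.25). Wnt8b fell from 1022 ± 85.4 to 5.18 ± 6.92 CPM, and Lhx5 from 296 ± 106 to 4.83 ± 5.96 CPM. Rspo1 fell from 554 ± 69.9 to 45.2 ± 9.31 CPM (log2 change -3.67 ± 0.64), and Lhx9 from 794 ± 129 to 19.9 ± 13.1 CPM (-5.46 ± 1.19). Rmst fell from 13479 ± 2718 to 1014 ± 314 CPM (log2 change -3.62 ± 0.57), and Col1a1 from 7020.3 ± 3605 to 71.9 ± 40.2 CPM (-6.61 ± 0.50). Of 6 radial glia genes, 3 fell and 3 did not pass (3 passing adjusted over the list alone, camera adjusted p = 0.198). Gli3 (log2 change -1.16 ± 0.12), Nes (-1.23 ± 0.16) and the Notch target gene Hes5 (-1.87 ± 0.0942) fell. Sox2 (0.18 ± 0.0916) did not pass. Of 5 astrocyte genes, 4 rose and 1 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.0136, and adjusted p = 0.233 with an estimated correlation), and of 6 oligodendrocyte lineage genes, 5 rose and 1 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.00919, and adjusted p = 0.233 with an estimated correlation). Of 6 newborn neuron genes, 4 rose and 2 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.122), including Dcx (log2 change 1.15 ± 0.11) and Sox11 (log2 change 0.50 ± 0.12). Of 8 microglia and macrophage genes, 5 rose, 2 fell and 1 did not pass (7 passing adjusted over the list alone, camera adjusted p = 0.183), with a rise of Laptm5 (log2 change 1.57 ± 0.21) and a fall of Cd68 (log2 change -0.52 ± 0.12). Of 10 fibroblast and mesenchyme genes, 8 fell and 2 did not pass (8 passing adjusted over the list alone, camera adjusted p = 0.00919, and adjusted p = 0.233 with an estimated correlation). The test called 187 of 318 genes tested, 88 higher and 99 lower at P1, and the genes named as passing had edgeR adjusted p-values of at most 0.00314.

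Within GABAergic neuron-like cells, P1 was compared with E15.5 beside the excitatory cells (5164–16911 cells and 699068–3797257 gene transcripts per sample). The class came from cluster 4, led by Ikzf1, Strip2 and Ppp1r1b with other genes of striatal projection neurons, and cluster 30, of whose 6495 cells 6210 came from the second P1 male. It is not the set of all inhibitory neurons: cluster 2 (163429 cells), led by Gad2, and clusters 11 and 12, with Gad1 among their leading genes, took no name and stayed outside, and cluster 4 has neither among its first 10. Lamp5 rose from 6.04 ± 2.14 to 782 ± 172 CPM, with an E15.5 level not above the mean probe's (8.004 CPM). Nrgn rose from 261 ± 31.6 to 5298 ± 969.7 CPM (log2 change 4.35 ± 0.22). Rprml rose from 54.1 ± 22.5 to 1044 ± 238 CPM (log2 change 4.29 ± 0.28), and Itpka from 199.9 ± 21.3 to 2409 ± 168 CPM (3.59 ± 0.13). Dusp14, a phosphatase gene, rose from 66.0 ± 9.60 to 1237 ± 145 CPM (log2 change 4.23 ± 0.21). An astrocyte gene rose with them, Aqp4 from 3.96 ± 3.05 to 92.1 ± 14.6 CPM. Col1a1 fell from 4221 ± 1979 to 151 ± 13.0 CPM (log2 change -4.80 ± 0.44), and Igf2 from 2309 ± 629 to 325 ± 75.6 CPM (-2.84 ± 0.25). Nrn1 fell from 142 ± 35.7 to 18.2 ± 4.25 CPM (log2 change -2.96 ± 0.28), and Fezf2 from 154 ± 44.4 to 18.7 ± 5.06 CPM (-3.04 ± 0.30). Prss12 fell from 911 ± 289.6 to 93.2 ± 20.9 CPM (log2 change -3.30 ± 0.38), and Zfp366 from 185 ± 48.1 to 27.0 ± 4.35 CPM (-2.78 ± 0.26). Rxfp1 from 9.89 ± 3.30 to 162 ± 64.4 CPM and Bdnf from 119.5 ± 17.8 to 9.26 ± 4.43 CPM, the gene of a neurotrophin, had the other sign when other cells were drawn for the clustering (log2 changes -0.39 and 0.21). Of 7 interneuron genes, 4 fell and 3 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.265). The peptide genes Vip (log2 change -2.05 ± 0.31) and Cort (log2 change -0.85 ± 0.14) fell, and Gad1 (log2 change 0.10 ± 0.0945) did not pass but was a fall past the threshold at a resolution of 1.5 (-0.42, adjusted p = 0.000331). Gad2 (log2 change -0.48 ± 0.12) fell, but had the other sign per cell (0.20), with at least 40 transcripts per cell (0.30) and with another subsample (0.38), and did not pass at that resolution. Of 5 striatal genes, 4 rose and 1 fell (5 passing adjusted over the list alone, camera adjusted p = 0.265). The dynorphin precursor gene Pdyn (log2 change 1.41 ± 0.13) rose, and the fall of Meis2 (log2 change -0.51 ± 0.10) turned per cell (0.18). Of 6 newborn neuron genes, 6 fell (6 passing adjusted over the list alone, camera adjusted p = 0.129), including Sox11 (log2 change -1.25 ± 0.0828) and Tubb3 (log2 change -0.78 ± 0.0867), a neuronal tubulin gene. Of 9 neuronal maturation genes, 4 rose, 2 fell and 3 did not pass (6 passing adjusted over the list alone, camera adjusted p = 0.265), and of 7 pan cortical excitatory genes, 1 rose, 4 fell and 2 did not pass (5 passing adjusted over the list alone, camera adjusted p = 0.422). Of 5 astrocyte genes, 4 rose and 1 did not pass (4 passing adjusted over the list alone, camera adjusted p = 0.19), and of 12 fibroblast and mesenchyme genes, 2 rose, 9 fell and 1 did not pass (11 passing adjusted over the list alone, camera adjusted p = 0.148).

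The test called 272 of 347 genes tested, 130 higher and 142 lower at P1, and the genes named as passing had edgeR adjusted p-values of at most 0.00191. Per cell, the split was 180 higher and 55 lower. With at least 40 transcripts per cell 76 genes passed, and 90 with other cells drawn for the clustering, each with 9 of 12 samples. Calls did not hold per cell for Tubb3 and Cort. At 40 transcripts they were lost for Bdnf, Aqp4, Pdyn, Zfp366, Fezf2, Tubb3, Vip and Meis2, and Cort (0.0525) and Rxfp1 (-0.33) had the other sign. With other cells drawn, calls were lost for Pdyn, Zfp366, Vip, Cort and Meis2.

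Whether deep-layer genes were found in the same excitatory cells was measured as the log2 ratio of cells holding both genes to the number expected if the genes were independent, in cells thinned to 50 transcripts. Bcl11b and Satb2, transcription factors of subcerebral and of callosal neurons, met in fewer cells than independence gives, with a ratio of -0.44 ± 0.0281 at E15.5, -0.53 ± 0.0823 at E18.5 and -0.77 ± 0.018 at P1 (SD, n = 4), or -0.11, -0.16 and -0.21 without thinning. At the same ages the corticothalamic genes Tle4 and Foxp2 met more often, at 0.85 ± 0.0455, 1.38 ± 0.0807 and 1.61 ± 0.0387. Unthinned these were 0.67, 1.05 and 1.27. Tle4 and Fezf2 stood at 0.42 ± 0.035, 0.86 ± 0.0633 and 1.08 ± 0.0429, or 0.41, 0.73 and 0.89 unthinned. Fezf2 and Bcl11b stood at 0.38 ± 0.00594, 0.72 ± 0.0613 and 0.86 ± 0.0749, or 0.22, 0.56 and 0.75 unthinned. Foxp2 and Cux2, an upper layer gene, stood at -0.98 ± 0.11, -1.77 ± 0.18 and -2.39 ± 0.30, or -0.51, -1.01 and -1.45 unthinned. The mix of sub-clusters changed with age, which the ratios cannot tell from a change within a cell type. Of 24 tests over 12 pairs and 2 steps of age, 0 passed after adjustment by the exact two-sided permutation test of 4 samples against 4. In 8 of them the ages did not overlap and p was 0.0286, the smallest that 70 splits allow, or 0.0857 adjusted. These were both steps for Tle4 with Fezf2, Tle4 with Foxp2 and Foxp2 with Cux2. The others were the earlier step for Fezf2 with Bcl11b and the later for Bcl11b with Satb2.

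**Figure D3:**
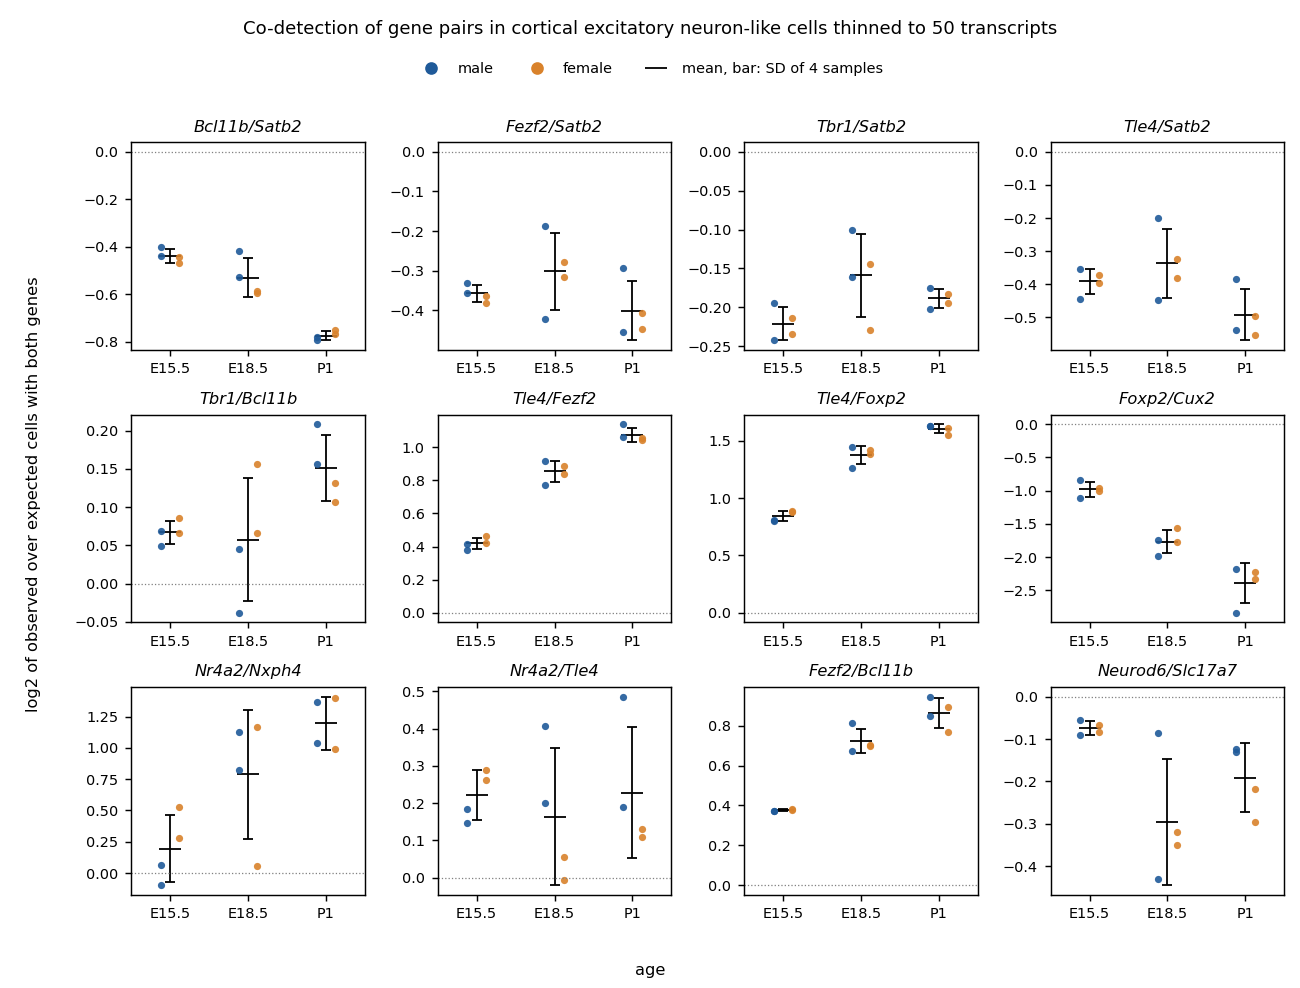
Log2 ratio of observed to expected cells holding both genes of a pair, for 12 pairs in cortical excitatory neuron-like cells thinned to 50 transcripts, at E15.5, E18.5 and P1, with a point per sample (male blue, female orange) and the mean and SD of 4 samples. Tle4 and Foxp2 went from 0.85 ± 0.0455 at E15.5 to 1.61 ± 0.0387 at P1.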

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

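The tests of library depth and of developmental stage below, and the use of quartiles, were chosen only after the results were seen. Among 56 groups of 4 samples, 4 held a sample far from the others by Dixon's test, where chance gives about 2.8. The first E12.5 female had 6139452 gene transcripts and 89.96% of its cells with at least 20 transcripts. The share of cells with at least 20 transcripts was 98.0% in the first E18.5 male and 94.7% in the second P1 male. Features outside the panel genes also carried transcripts, above the 3 that a count of 0 allows. The deprecated codeword held 126353, or 82.5 times the mean of a negative control probe and more than 101 of the 347 genes, with 2599–11630 per section. The 125 unassigned codewords held 92758 and the 41 negative control codewords 17868, which per feature is 0.484 and 0.284 times a negative control probe.

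The sex difference varied with age in excitatory cells, by edgeR's test of the interaction, for 31 of 347 genes (90 at an unadjusted p under 0.05). In whole sections it did for 1 (53 unadjusted). The smallest edgeR adjusted p-values were those of Id2 (0.00145), Mapt (0.00145), Dpy19l1 (0.00159), Syndig1l (0.00281) and Cspg5 (0.00625). The gene in whole sections was Neurod6 (edgeR adjusted p = 0.0352), with a log2 male minus female difference of 1.21 at E12.5 and -1.33 at P1. For 30 of the 31 genes both P1 males lay on one side of both P1 females, 19 of the 31 being higher and 12 lower in P1 males, and for 30 the difference had opposite signs at E12.5 and P1, which a choice of genes by the interaction favours. Over the 316 other genes the P1 and E12.5 differences correlated at r = -0.343. At P1 it had the same sign as in excitatory cells for 31 genes in corticothalamic-like cells, 30 in subplate-like, 30 in GABAergic neuron-like and 28 in radial glia-like cells, and 31 in whole sections, with a median of 0.695, 0.326, 0.495 and 0.515 times its size in the last 4.

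At P1 the tables argue against library depth: the deepest and the shallowest P1 library are both male, yet over all 347 genes tested the male minus female differences of separate P1 pairs correlated at a mean r of 0.706 (0.671 and 0.741), where depth needs a negative r; genes are not independent replicates. At P1 the tables also argue against another makeup of excitatory types, since within corticothalamic-like cells alone the difference of the 31 genes had a median of 1.01 times that in all excitatory cells (quartiles 0.861 and 1.14). Neither depth nor makeup is settled at E12.5, where the class held a median of 47 and 130 transcripts per cell in the females against 178 and 224 in the males. Averaged within sub-clusters 17, 19, 21 and 23, the E12.5 difference of the 31 genes was a median of 0.817 times that in the class, with quartiles of 0.686 and 0.941 on both sides of the bound of 0.8 set beforehand, so that makeup stays open there. A difference in developmental stage stays open too: over the 31 genes the P1 difference went with the change from E15.5 to E18.5 at r = 0.476 (95% interval 0.15 to 0.71), and over the 316 others, which leave out the pattern's own genes, at -0.0619. The E12.5 difference went with the change from E12.5 to E15.5 at r = 0.0129 over the 31 (-0.34 to 0.37), an interval too wide to decide. A slide or processing run shared by the samples of one sex and age, for which the labels give no name, and sex itself were not tested and stay open as candidate explanations.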

How the results depend on the processing

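The settings without low-depth libraries, without both P1 males or both E12.5 females, without tissue outside the brain, without sub-clusters 17, 19, 20 and 23 and without genes of other cell types, and all settings for the count of genes of other cell types, were chosen only after the results were seen. Where the reported count was above 0, 205 of 216 counts under an alternative lay within 1.5 times of it; the other 74 compare 0 with 0 and say little. Of 7064 values of named genes 6841 stayed on their side of the threshold with their direction, 157 fell short of it, 40 passed it and 26 turned. With 1 sample left out, whole sections gave 228–252, 202–223 and 97–134 genes over the 3 steps of age and excitatory cells 182–227, 134–159 and 57–90, the lowest without the first P1 male. Corticothalamic-like cells gave 244–260, subplate-like 170–200, radial glia-like 170–184 and GABAergic neuron-like cells 251–266, and 0 genes between the sexes were called in any such fit. Over all settings the counts spanned 182–259, 148–261, 61–151, 153–234, 96–213, 40–126, 226–267, 166–205, 152–195 and 76–275 in that order, and between the sexes edgeR called 0 in each, with 12 and 7 genes at an unadjusted p under 0.05 and 0 called by DESeq2. Counts of genes are limited by depth where a gene lies near the probes' level, and 274–338 of 347 genes per section lay above the highest negative control probe.

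With the number of cells as library size the count was 148 in whole sections from E15.5 to E18.5 (146 of them among the reported calls), and in excitatory cells 96 in that step (90) and 50 from E18.5 to P1 (45), and of genes of other cell types inside excitatory cells 26 were called between E15.5 and P1, 25 of them among the 41 reported. This setting keeps the rise in transcripts per cell, and its median log2 change of all genes tested was 0.23, 0.21 and 0.44 over the steps in sections, 0.46, 0.30 and 0.46 in excitatory cells, and 0.81, 1.00, -0.16 and 0.64 in the 4 classes, against -0.0685 to 0.15 as reported. Without TMM factors that median was 0.36 and 0.11 in the first and second step in sections, 0.32 and 0.24 in excitatory cells, and 0.42, 0.28, -0.17 and 0.11 in the classes. Turned per cell were, in corticothalamic-like cells, Tbr1 (log2 change 0.41, and 0.0206 without TMM factors), Tle4 (0.53), Nxph4 (0.62), Nrep (0.0101) and Slc17a7 (0.34), in subplate-like cells Tbr1 (0.23), Tle4 (0.35) and Tubb3 (0.86), and in GABAergic neuron-like cells Gad2 (0.20) and Meis2 (0.18).

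Without both P1 males, which leaves 2 P1 samples, the step from E18.5 to P1 gave 61 genes in sections (59 among the reported) and 40 in excitatory cells (36), and 57 there without the first P1 male. GABAergic neuron-like cells gave 76 genes with at least 40 transcripts per cell and 90 with another subsample, when the class held 40654 and 34718 cells in place of 130039 and only 9 of 12 samples entered. There Rxfp1 (-0.33), Cort (0.0525) and Gad2 (0.30) turned at 40 transcripts, Rxfp1 (-0.39), Bdnf (0.21) and Gad2 (0.38) with another subsample, and Gad1 (-0.42) at a resolution of 1.5. Without tissue outside the brain, Gad1 (-0.0697) and Penk (0.0658) turned in the step from E12.5 to E15.5, and Hapln1 (1.19) and Pdgfra (0.60) in the next. In excitatory cells from E12.5 to E15.5, Nr4a2 turned with another subsample (-0.15) and without sub-clusters 17, 19, 20 and 23 (-0.94), a setting in which sub-cluster 21, led by Lhx9, gave 1935 of 2054 E12.5 cells, and Rprm (-0.0857) and Bcl11b (-0.49) without both E12.5 females. The causes were not tested where the setting itself does not show them. The list calls went from 11 to 0 of 227 with an estimated correlation, and fry, which asks only whether a list's genes move one way, called 125.

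Replicate numbers did not pair the samples: deviations from group means of same-numbered samples correlated at -0.43 to 0.43 in sections (6 of 28 group pairs over 0.1) and at -0.29 to 0.47 in excitatory cells (12 of 28). With the replicate block, sections gave 247, 227 and 121 genes and excitatory cells 195, 162 and 92, the 4 classes 259, 193, 185 and 275, and the sexes 0. Of the named genes only Ppp1r1b in sections from E18.5 to P1 lost its call under the block. The 10 comparisons of ages were set against other splits of the same samples. Fitted on their 8 samples without sex, the real ages gave 231, 254 and 158 genes in sections, 187, 228 and 93 in excitatory cells and 244, 176, 233 and 281 in the 4 classes. In each only 1 of 35 splits, the real one, gave as many, with at most 0 genes in the others. Each other split mixes samples of both ages, so that the difference between ages widens its spread and holds its count down. These splits therefore cannot exclude chance for the ages. For the sexes the real split called 0 genes, which all 100 of 100 splits drawn within ages reach by design (at most 2 in sections and 0 in excitatory cells), so that these splits decide nothing. For pairs, 369 of 396 values moved by less than the spread between samples and 27 by more.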

Other observations

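The settings with other library sizes below, and the condition that leaving out cells must move a call, were chosen only after the results were seen. Among the pairs of genes, Satb2 stood below independence also with Fezf2 (log2 ratio -0.36 ± 0.0209, -0.30 ± 0.0973 and -0.40 ± 0.0751 at E15.5, E18.5 and P1, SD, n = 4), Tle4 (-0.39 ± 0.0388, -0.34 ± 0.11 and -0.49 ± 0.077) and Tbr1 (-0.22 ± 0.0212, -0.16 ± 0.0537 and -0.19 ± 0.0123), in excitatory cells thinned to 50 transcripts. Tbr1 and Bcl11b stood at 0.0671 ± 0.0149, 0.0573 ± 0.0801 and 0.15 ± 0.0433. The subplate gene Nr4a2 met Nxph4, another subplate gene, at 0.19 ± 0.27, 0.79 ± 0.52 and 1.20 ± 0.21, and Tle4, a corticothalamic gene, at 0.22 ± 0.0668, 0.16 ± 0.18 and 0.23 ± 0.18. Neurod6 and Slc17a7, both genes of excitatory neurons at large, stood at -0.0741 ± 0.0159, -0.30 ± 0.15 and -0.19 ± 0.0814. At E12.5, where most cells of the class lie in sub-clusters led by genes of progenitors or other neurons, Bcl11b with Satb2 was at 0.16 ± 0.16, Fezf2 with Satb2 at 0.53 ± 0.20, Tle4 with Foxp2 at 0.72 ± 0.14 and Foxp2 with Cux2 at 0.36 ± 0.16, and these values entered no test.

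Genes of astrocytes, oligodendrocytes, microglia, endothelium, mural cells and fibroblasts changed between E15.5 and P1 inside excitatory cells, 14 higher and 27 lower of 51 measured. With the number of cells as library size 26 were called, 15 higher and 11 lower, with 16 of the 27 falls no longer called, and without TMM factors 34, 15 higher and 19 lower. The 46 genes of the lists other than mural, which had no cluster of its name, had a median level at P1 of 0.392% of that in the cluster named for their list. Transcripts of neighbouring cells counted in neurons are a candidate explanation: over the 51 genes the log2 change in excitatory cells correlated with that in all other cells at r = 0.747 across genes, and 30 of the 41 called genes moved the same way in both, such as Olig1 (1.93 and 1.73), while Cd53 (-1.86 and 0.20) moved apart. Merged cells of very high totals stay open: 0% of the 41 calls were lost without the 1% of cells with the most transcripts, but these held a median of 4.36% of the transcripts of the 51 genes, and the setting moved log2 changes by a median of 0.0172 and no call, too little to decide. Expression by the neurons themselves stays open: the shares of the source level differed between genes of a list by a median fold of 2.53, between the bounds of 2 and 4 set beforehand, from 1.75 for microglia, 1.89 for endothelium and 2.20 for oligodendrocytes to 4.43 for astrocytes and 6.70 for fibroblasts.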
